A study of Mus musculus with 12 samples.

How the data were processed

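C2C12 myotubes differentiated for 3 days were left untreated or treated with 10 ng/ml LIF or with C26 conditioned medium as 1 part in 3, and sampled after 4, 8 and 24 h, per the labels' protocols. Total RNA of 3 wells was pooled per array and 12 Affymetrix mouse gene 1.0 ST arrays were run, 1 per agent, arm and time, per the series' design text. Samples were grouped by their titles.

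The deposited table holds log2 expression values, 1 per Entrez gene, for 21187 genes. RMA was applied per the submitters' processing notes; its version, the probe set definition and the genome build are not given in the sources used here. The authors rounded log2 values to 1 decimal in the LIF experiment and to 2 decimals in the conditioned medium experiment, as the values show. Rounding makes ties in the LIF experiment, where a difference is a multiple of 0.1. Array medians show that the 4 h and 8 h arrays and the 24 h arrays of each experiment do not share a scale, so levels were not compared across them. The background range of an array lies under the level that 5% of its olfactory and vomeronasal receptor genes exceed. The authors also deposited tables of signed fold changes, treated over untreated, per the file headers; these lay within rounding of the log2 differences for 100% of the genes and were used only as an alternative. A further 12 columns of per-sample values in those tables were not used. Gene symbols were updated through the Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, used for names only: 20819 identifiers matched, 1943 symbols were renamed and 15 genes had no symbol.

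Values were used as deposited, with no filter on dim genes and no further normalization. The log2 change at each time was the treated minus the untreated value of that agent, with no test, and genes past 2-fold were counted beside the same count between untreated arrays. The main fit used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend) on all 12 arrays with the treated and untreated pair as a block and a treatment effect per agent, which leaves 4 residual degrees of freedom, from how a response varies over the times. Contrasts were the LIF response, the conditioned medium response, their difference and their mean. A further fit added a treatment by time effect shared by the agents, with 2 residual degrees of freedom, for 24 h minus 4 h. P values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05.

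Gene lists were tested with camera at a correlation of 0.01 in the LIF, conditioned medium and difference contrasts, with adjustment over the 21 lists of a contrast, and camera with an estimated correlation and fry (with statmod 1.5.0 installed) as alternatives. The 17 pathway lists, with their genes, were STAT3 feedback and targets, acute phase proteins, NF-kB targets and chemokines, atrophy ligases with FoxO targets and autophagy, proteasome subunits, sarcomere and muscle contraction, myogenic regulators, immediate early and ERK pathway genes, interferon response, proliferation, amino acid response and unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, TGF-beta and activin targets, extracellular matrix and matrix proteases, and glucocorticoid targets. The 4 marker lists were fibroblasts and unfused mononucleated cells, adipocytes, colon carcinoma epithelium, and macrophages and leukocytes. At each time the median of a list was ranked among 10000 random lists matched on mean level in 20 bins. Agreement between agents was the Pearson and Spearman correlation across genes, with no p.

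The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule took, for each agent, the 10 genes with the largest rise and the 10 with the largest fall past the threshold with the same sign at all 3 times, or those with the smallest p where fewer passed; the 5 highest and 5 lowest past the threshold for the difference, the mean and 24 h minus 4 h; the 5 highest and 5 lowest at each time; up to 4 members of each list; and 22 genes named in advance. Predicted genes, features with no or several symbols, receptor families of smell, microRNA and small nucleolar RNA genes and histones were left out of the ranked parts, 3229 genes in all, and kept in the counts. Not every gene that the rule picks is named in the text. Other members of the called sets (such as Irf9, Il4ra, Casp4, Hgf, Bdkrb1, Ccl8 and Ccnd1) are named as examples chosen after their values were seen.

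Alternatives were leaving out the dimmest 25% or 50% of genes, eBayes without a trend, robust eBayes, quantile normalization of the 12 arrays, centring on the median, a threshold of 0.10, fold changes of 1.5 and 3, the authors' deposited fold changes, each time left out, and only the 6 arrays of an agent. The fits were tested on simulated data with 200 changed genes among 21187 in each comparison. At a log2 change of 0.5 the share recovered was 90.0% for LIF, 84.8% for conditioned medium, 59.7% for the difference, 100% for the mean and 40.8% for 24 h minus 4 h, and at a log2 change of 1 it was 100% in each but the last, with 95.4%. Unchanged genes called were 7, 11, 9, 3 and 23 in the same order. In the list test a simulated shift of 0.5 in 1 of 21 lists was called, and 0 of the others were. The simulated changes were the same at every time affected and the noise was independent. Measured responses varied over the times, so the shares do not give the power for real genes. Usp18, with a mean change of 2.23 with conditioned medium, missed the test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.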

Results

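The series measured gene expression in C2C12 myotubes, multinucleated muscle cells formed in culture from a mouse myoblast line, after 3 days of differentiation. Cultures received leukemia inhibitory factor (LIF), a cytokine of the interleukin-6 family that signals through JAK kinases and STAT3, at 10 ng/ml, or medium conditioned by C26 cells as 1 part in 3 of the culture volume. C26 is a mouse colon carcinoma line used as a model of cancer cachexia. Each agent had its own untreated cultures, and both arms were sampled at 4, 8 and 24 h. The series title puts the question as the place of LIF in the wasting caused by this tumour. RNA of 3 wells was pooled for each of the 12 arrays, with 1 array per arm and time. No difference at a single time therefore has a replicate check, and the pools hide the spread between wells. Adjusted p values below, except those for 24 h minus 4 h, come from a fit that treats the times as repeats. Times are not replicates, and such a p measures how alike a change was at 4, 8 and 24 h. For 24 h minus 4 h the agents serve as the repeats of each time. They are not replicates either, and that p measures how alike the shift was with LIF and with conditioned medium.

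The arrays gave values for 21187 genes. The median log2 level was 6 in the LIF experiment at 4 and 8 h and 5.5 at 24 h, and between 6.71 and 6.74 and then 6.14 in the conditioned medium experiment. Between 61.8% and 69.7% of the genes of an array lay above the upper range of 1288 olfactory and vomeronasal receptor genes, which muscle cells are not known to express and which stand here for the background signal. In untreated arrays the median over genes of the 24 h minus the 4 h value was -0.50 in the LIF experiment. It was -0.54 in the conditioned medium experiment. Between the untreated 4 h arrays, conditioned medium minus LIF experiment, the median over genes was 0.65. Changes with treatment were therefore taken only between the treated and the untreated array of one agent and time. Untreated arrays were also compared for the background counts, and ranks were compared between the experiments for the interferon list.

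With LIF the lubricin gene Prg4, a secreted proteoglycan, had the highest change at 8 h and 24 h, with log2 differences of 1.3, 1.9 and 2.7 at 4, 8 and 24 h. The serine protease inhibitor gene Serpina3n was higher by 1.0, 1.5 and 0.8, and Socs3, the feedback inhibitor of JAK and STAT3 signalling, by 0.7, 0.8 and 1.1. Averaged over the times the values were 1.97 ± 0.23 (SE) for Prg4, 1.10 ± 0.13 for Serpina3n and 0.87 ± 0.11 for Socs3. Serpina3n lay in the background range in all 3 untreated LIF arrays, so the size of its change is uncertain. Receptor subunits of type 2 cytokines were also higher at every time, Il4ra by 0.70 and Il13ra1 by 0.67 on average, as were the oncostatin M receptor Osmr by 0.57 and the alarmin cytokine Il33 by 0.57. The inflammatory caspase gene Casp4 stood at 0.70, the tetraspanin gene Cd53 at 0.53, the DNA-sensing adaptor Sting1 at 0.53, Ugdh, which makes a precursor of hyaluronan, at 0.33, and the autophagosome protein gene Map1lc3b at 0.27. All of these but Il4ra and Osmr were the 10 higher genes with the smallest p.

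Among the genes that were lower with LIF at every time, those with the smallest p were the apolipoprotein L gene Apol10a (-0.60), the chemokine genes Ccl17 (-0.57) and Cx3cl1 (-0.53), Tmc3 (-0.47), the transcription factor gene Trp63 (-0.33), the thrombin receptor gene F2r (-0.33), and Megf10, Cobll1, Jam2 and Sh3bp4, each at -0.30. Apol10a belongs to a family of near-identical genes that an array may not separate and lay at a mean level of 3.48, so its value is uncertain. None of the 20 genes with the smallest p passed the test: limma called 0 of 21187 genes at an adjusted p of 0.05 for LIF, with 1445 genes at an unadjusted p under 0.05 where chance gives 1059. The smallest adjusted p was 0.0559, shared by 10 genes, among them Prg4, Serpina3n, Socs3, Casp4, Il33 and Apol10a. At a threshold of 0.10 limma called 28 genes, 19 higher and 9 lower. It called 12 with robust variances, 12 after quantile normalization, 8 without the dimmest 25% of genes, and 11 with noise added within the rounding of the LIF values. It called 0 without any 1 of the 3 times, without a variance trend or in the 6 LIF arrays alone.

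By size alone, 13 genes differed at least 2-fold with LIF at 4 h (9 higher, 4 lower), 10 at 8 h (9 higher, 1 lower) and 30 at 24 h (22 higher, 8 lower). As a background, 28 genes differed as much between the untreated 8 h and 4 h arrays of that experiment. At 4 h the highest genes beside Prg4 were Pcdhga2 (1.5), AA792892 (1.2), Pcdha11 (1.1) and Dppa3 (1.0), and the lowest were Zfp931 and Ssxb1 (-1.0 each) and Tnfsf15, Pcdhgb4 and Ugt1a2 (-0.9 each). At 8 h Obox2 (1.2), Zfp931 (1.1) and Cyp2c66 (1.1) followed Prg4 and Serpina3n, and Defb12 (-1.1), Trav12-1 (-0.9), Oas1g (-0.9), Prl3d1 (-0.8) and Igkv10-94 (-0.8) were lowest. At 24 h the highest were Prg4, the granzyme inhibitor genes Serpinb9g (2.3) and Serpinb9f (1.6), the prostaglandin F receptor gene Ptgfr (1.5) and the angiotensin-converting enzyme gene Ace (1.4), and the lowest were Appbp2os (-1.4), the collagen gene Col8a1 (-1.1), the growth factor gene Ereg (-1.1), Gmfg-ps (-1.1) and the matricellular gene Ccn2 (-1.0). Protocadherin genes (Pcdha, Pcdhga, Pcdhgb) and the Serpinb9 and Oas1 genes have near-identical copies, so those calls are uncertain. Pcdhga2, Pcdha11, Zfp931, Ssxb1, Obox2, Cyp2c66, Oas1g, Serpinb9g and Serpinb9f also lay in the background range in all 3 untreated LIF arrays, and AA792892 and Ugt1a2 in 2, which leaves the sizes of their changes uncertain.

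Of the gene lists fixed in advance, 6 of 21 passed camera for LIF, 3 higher and 3 lower, and 0 passed with an estimated correlation or with fry. In the STAT3 list, with 36 of 36 genes measured, 0 genes passed over all genes and 9 passed adjusted over the list alone: Socs3, Il4ra, Osmr, the NF-kB cofactor gene Bcl3, Cebpd, Hif1a and Timp1 rose, and Rgs16 and Tnfrsf12a fell. The list had a median change of 0.08 and a camera adjusted p of 3.23e-05, and adjusted p = 0.553 with an estimated correlation. The glycolysis and hypoxia list rose with a median of 0.07, adjusted p of 7.13e-09 and adjusted p = 0.553 with an estimated correlation. Its 27 of 31 members above 0 included 5 that rose adjusted over the list alone, namely the carbonic anhydrase gene Car12 (0.80), the pyruvate dehydrogenase kinase gene Pdk1 (0.37), Tpi1, Egln3 and Ndrg1. The list of atrophy ligases, FoxO targets and autophagy genes rose by camera (adjusted p of 5.92e-04; adjusted p = 0.553 with an estimated correlation), and the 4 members that rose adjusted over the list alone were not ubiquitin ligases: Bnip3 (0.50) and Map1lc3b act in autophagy, and Mt1 and Mt2 (0.27) are metal-binding metallothioneins. Without 24 h the adjusted p was 0.231 for the STAT3 list and 0.289 for the atrophy list.

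The lists that fell with LIF were the TGF-beta and activin targets, the immediate early and ERK pathway genes and the sarcomere genes. In the first, with a median of -0.20 over 21 measured genes, 8 genes fell and 1, Klf10, rose adjusted over the list alone; Ccn2 stood at -0.60 ± 0.21 and the activin subunit gene Inhba at -0.43 ± 0.12. Its camera adjusted p was 1.73e-05, and adjusted p = 0.553 with an estimated correlation. Of 36 immediate early and ERK pathway genes 27 lay below 0, and 5 fell adjusted over the list alone, namely the growth factor genes Ereg (-0.63) and Hbegf (-0.60), Dusp4, Etv4 and Plau (camera adjusted p of 7.40e-07; adjusted p = 0.553 with an estimated correlation). The 55 sarcomere genes had a median of -0.03 and 0 of them passed adjusted over the list alone by limma, with a camera adjusted p of 5.92e-04 and adjusted p = 0.562 with an estimated correlation. The sarcomere p was 0.103 without 4 h and 0.119 without 8 h. In these 3 lists, as in the rising ones, 0 genes passed over all genes.

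For LIF the other lists missed the camera threshold. Adjusted p was 0.385 for acute phase proteins, where Serpina3n rose adjusted over the list alone, 0.727 for NF-kB targets and chemokines (Cxcl5 and Il1b rose and Tnfaip3 and Csf1 fell adjusted over the list alone). It was 0.541 for proteasome subunits, 0.727 for myogenic regulators (adjusted over the list alone Id1 and Myf5 rose and Msc and Heyl fell) and 0.314 for the interferon response. It was 0.894 for proliferation, 0.422 for amino acid and unfolded protein response genes, 0.511 for cholesterol synthesis, 0.540 for oxidative phosphorylation, 0.251 for extracellular matrix and 0.894 for glucocorticoid targets. In the matrix list Adamts5, Vcan and Lox rose and Tnc fell adjusted over the list alone, and in the cholesterol list Ebp rose. In the glucocorticoid list Hsd11b1, Angptl4 and Cebpa rose while Sult1a1 and Tsc22d3 fell adjusted over the list alone. Cxcl5 and Sult1a1 lay in the background range in all untreated and all treated LIF arrays, so their changes are uncertain. The glucocorticoid list had a median of -0.05 and a mean of 0.02 with camera pointing down, and the proliferation list a median of -0.02 and a mean of -0.01 with camera pointing up. Without 24 h the proliferation list was called higher with LIF (camera adjusted p of 7.39e-11) and the cholesterol list lower (0.00451). Without 4 h the proliferation list was called lower (0.0157). These p values used a correlation of 0.01, where the correlation estimated with all times was 0.84 for proliferation and 0.66 for cholesterol synthesis.

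Conditioned medium raised genes of the interferon response, which encode antiviral proteins and the factors that switch them on. The oligoadenylate synthetase-like gene Oasl2 was higher by 1.7, 3.19 and 1.82 at 4, 8 and 24 h (mean 2.24 ± 0.23, limma adjusted p of 0.0143), the antiviral gene Ifit1 by 2.04, 3.23 and 1.20 (mean 2.16 ± 0.28, adjusted p of 0.025), and Rtp4 by 2.22 on average. The immunity-related GTPase gene Irgm2 rose by 1.75, from untreated values in the background range in 2 of 3 arrays, the transcription factor genes Irf7 by 1.73 and Irf9 by 1.44, Xaf1 by 1.66, the nucleic acid sensor Zbp1 by 1.62 and the secreted glycoprotein gene Lgals3bp by 1.49. Usp18 (2.23, adjusted p of 0.0586), Ifit3 (2.16, adjusted p of 0.0633) and Ifi44 (2.03, adjusted p of 0.0557) missed the test, with values at 8 h of 3.70, 3.72 and 3.42. In the LIF experiment the mean values were 0.10 for Oasl2, -0.03 for Ifit1, 0.07 for Rtp4, 0.07 for Irgm2 and 0.00 for Irf7, while Xaf1 stood at 0.57. Ifit1, Rtp4 and Irgm2 lay in the background range in all 6 LIF arrays, and a small change of theirs with LIF would not be seen. The 20 members of the interferon list above background in all untreated LIF arrays had a median change with LIF of 0.02.

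In the interferon list 36 of 39 genes were measured, 34 lay above 0 and the median change with conditioned medium was 0.59. Over all genes 10 passed, all higher, and 24 rose adjusted over the list alone, among them Oasl2, Ifit1, Irf7, Xaf1, the guanylate-binding genes Gbp2 and Gbp3, and the antigen presentation genes Tap1, B2m, H2-K1 and H2-D1. The camera adjusted p was 2.56e-39, and adjusted p = 0.173 with an estimated correlation. At 4, 8 and 24 h the list median was 0.23, 0.92 and 0.47, higher at each time than in all 10000 random lists of like level. Ifit, H2 and Oas genes have near-identical relatives, and a count that includes them is uncertain.

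**Figure D1:**
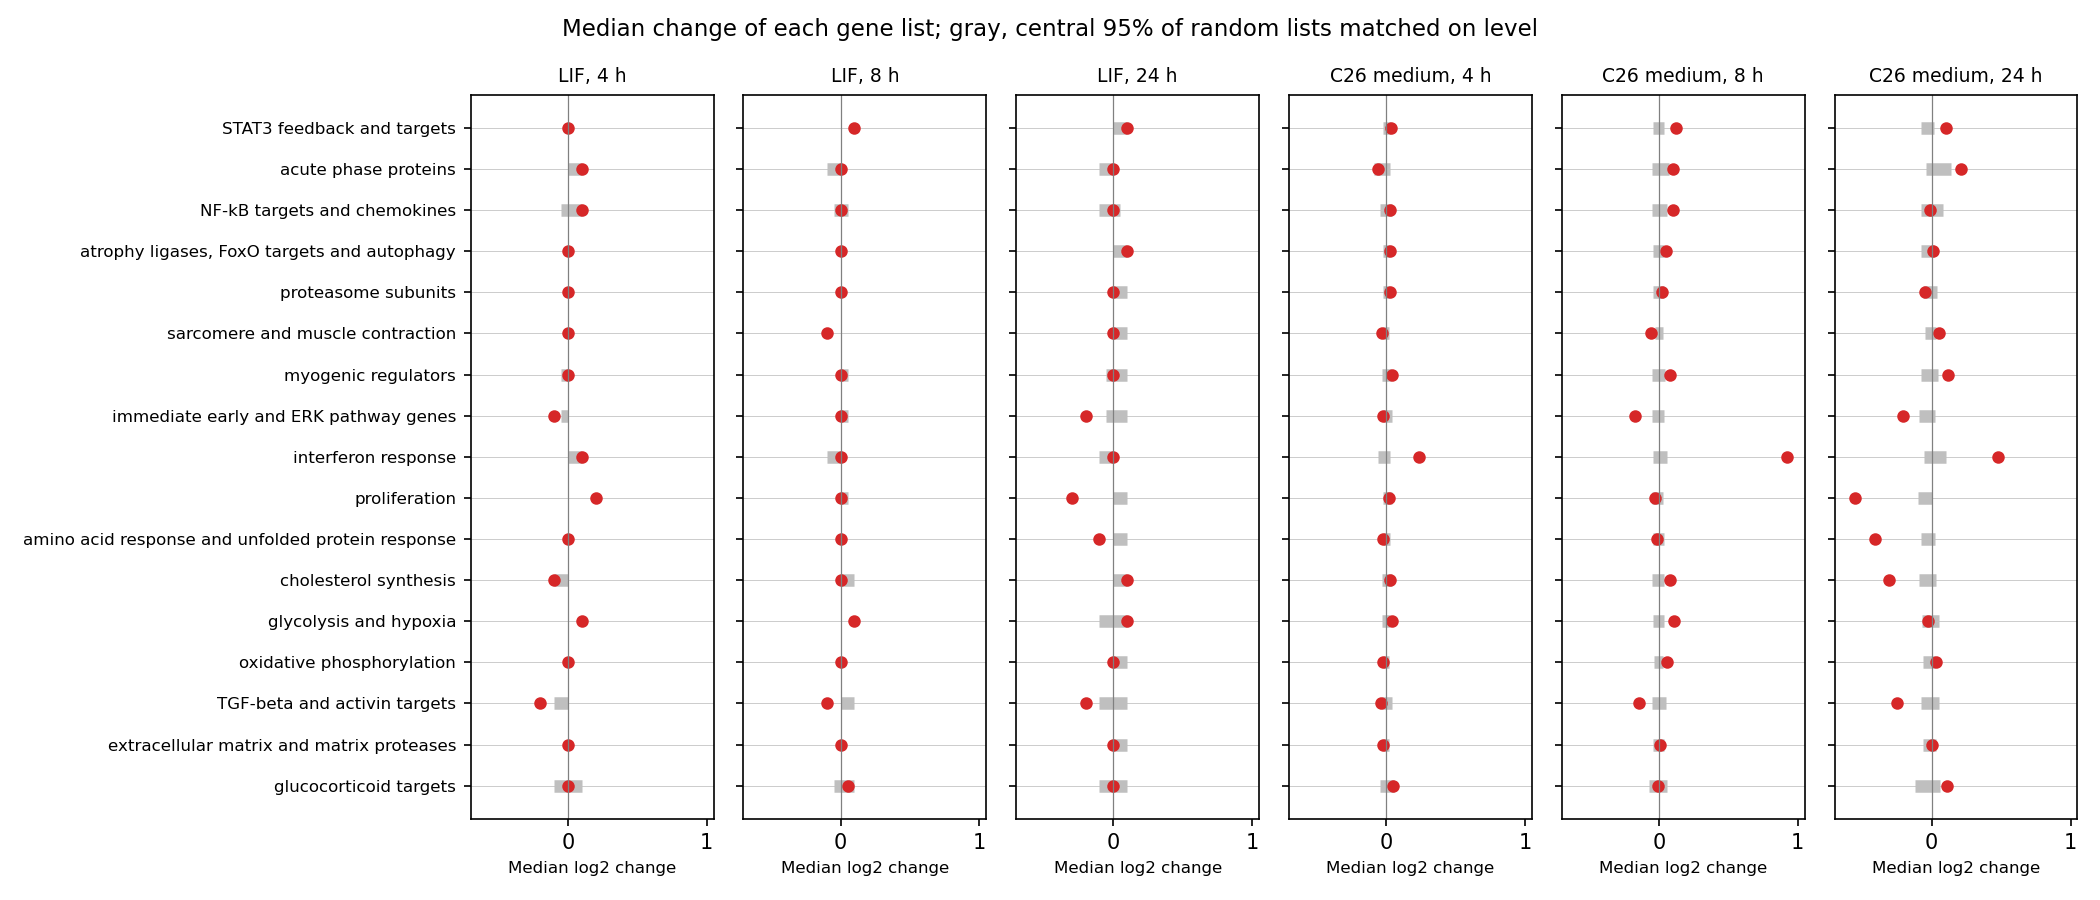
Median log2 change of each pathway list, treated minus untreated, at 4, 8 and 24 h for LIF and for C26 conditioned medium (1 array per arm and time), with the central range of random lists in gray. The interferon list reached 0.92 at 8 h with conditioned medium, and the proliferation list stood at -0.30 with LIF and -0.55 with conditioned medium at 24 h.

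Conditioned medium also raised chemokine genes that attract monocytes and eosinophils. Ccl7 was higher by 0.89, 1.67 and 2.02 at 4, 8 and 24 h (mean 1.53 ± 0.17, adjusted p of 0.0143), Ccl2 by 0.70, 1.27 and 1.36 (mean 1.11 ± 0.13, adjusted p of 0.0156), Ccl11 by 1.31 and Ccl8 by 0.86 on average. Prg4 rose by 1.62 ± 0.23 (adjusted p of 0.0301), the bradykinin receptor gene Bdkrb1 by 1.08, Bcl3 by 0.80, Casp4 by 0.78, the hepatocyte growth factor gene Hgf by 0.57, the matrix proteoglycan gene Vcan by 0.34 and Ugdh by 0.33. For NF-kB targets and chemokines 3 of 28 genes passed over all genes, Ccl7, Ccl2 and the adhesion molecule gene Vcam1. Adjusted over the list alone Cxcl5 also rose, from untreated values in the background range in all 3 arrays, and the cyclooxygenase gene Ptgs2 fell. The camera adjusted p of the list was 5.64e-04, and adjusted p = 0.147 with an estimated correlation.

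In all, limma called 46 genes for conditioned medium, 45 higher and 1 lower, with 1585 genes at an unadjusted p under 0.05. The lower one was the lens crystallin gene Cryge (-0.46, mean level 2.48, in the background range). Of the 46 genes 8 lay in the background range in at least 1 untreated array, 5 of them in all 3. Gbp3 lay there in all 3, and the sizes of the changes of the 8 are uncertain. Other lower genes with the smallest p missed the test, among them the endothelin gene Edn1 (-1.10), Gpr176 (-0.68), the growth factor gene Pdgfb (-0.44), Klhdc8a (-0.43), Hdac7 (-0.41), Fat1 (-0.37) and Thbs1 (-0.22). The count of 46 fell to 1 without 4 h, to 0 without 8 h and to 0 without 24 h, and was 25 without the dimmer 50% of genes, 25 with robust variances, 76 at a threshold of 0.10 and 13 from the authors' deposited table of fold changes. It was 0 without a variance trend, in the 6 conditioned medium arrays alone, and after rounding the values to 1 decimal.

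By size, 16 genes differed at least 2-fold with conditioned medium at 4 h (16 higher, 0 lower), 72 at 8 h (64 higher, 8 lower) and 83 at 24 h (50 higher, 33 lower), against 5 between the untreated 8 h and 4 h arrays. At 4 h the highest were Ifit1, Usp18 (1.97), Rtp4 (1.92), Irgm2 (1.88) and Oasl2, and the lowest Trdv2-2 (-0.96), Pin4 (-0.94), Gprasp2 (-0.88), Appbp2os (-0.84) and Pcdha6 (-0.78). At 8 h Ifit3, Usp18, Rtp4 (3.45), Ifi44 and Ifit1 were highest and Edn1 (-1.46), Fabp5 (-1.33), Ccn2 (-1.32), Gask1b (-1.15) and the monoglyceride lipase gene Mgll (-1.12) lowest. At 24 h the highest were the corticosteroid-binding globulin gene Serpina6 (2.07), Prg4 (2.04), Ccl7 (2.02), Ccl11 (1.92) and Ptgfr (1.91), and the lowest the keratin gene Krt14 (-1.82), Klrb1a (-1.69), Edn1 (-1.64), Gask1b (-1.56) and Cth (-1.52), an enzyme of cysteine synthesis. Ifit3, Fabp5, Serpina6 and Appbp2os lay in the background range in all 3 untreated arrays and Pin4, Gprasp2, Irgm2 and Ptgfr in 2, so the sizes of their changes are uncertain.

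Camera called 13 of 21 lists for conditioned medium, 8 higher and 5 lower. It called 0 with an estimated correlation or with fry. Beside the interferon and NF-kB lists, the STAT3 list rose with a camera adjusted p of 9.50e-06 and adjusted p = 0.309 with an estimated correlation. In it Bcl3 was among the genes that passed over all genes, and adjusted over the list alone 11 genes rose, among them Socs3 (0.66), Il4ra (0.45), Osmr (0.44), Cebpb (0.27) and Cebpd (0.31), and Tnfrsf12a fell. Myogenic regulators rose with an adjusted p of 3.20e-05 and adjusted p = 0.147 with an estimated correlation; the 3 members that rose adjusted over the list alone were Id3, an inhibitor of myogenic factors, Snai1, a repressor, and Pax7, a satellite cell factor. The acute phase list (0.00428, and adjusted p = 0.403 with an estimated correlation) had 0 members past either adjustment by limma, and its p was 0.345 without 24 h. The atrophy list rose with an adjusted p of 0.00841 and adjusted p = 0.369 with an estimated correlation, and its single member that rose adjusted over the list alone was Txnip, a regulator of glucose uptake, at 0.33. Its p was 0.124 without 4 h and 0.104 without 8 h. The glycolysis and hypoxia list (0.00406, and adjusted p = 0.538 with an estimated correlation) had Car12 higher adjusted over the list alone, with a p of 0.224 without 4 h and 0.609 without 8 h. Oxidative phosphorylation (0.0475, and adjusted p = 0.571 with an estimated correlation) had 0 members past either adjustment, with a p of 0.630 without 8 h and 0.129 without 24 h.

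The 5 lists that fell with conditioned medium held growth factor, cell cycle and biosynthesis genes. Among immediate early and ERK pathway genes 30 of 36 lay below 0, with 9 that fell adjusted over the list alone, among them Hbegf (-0.67), Ereg (-0.62), Lif itself (-0.50) and the ERK phosphatase genes Dusp1, Dusp4 and Dusp6, and 1 that rose, Spry2 (camera adjusted p of 6.75e-11; adjusted p = 0.314 with an estimated correlation). Among TGF-beta and activin targets 9 of 21 fell adjusted over the list alone, with Ccn2 at -0.97 ± 0.21 and Inhba at -0.55, and Tgfbi rose (1.33e-06; adjusted p = 0.323 with an estimated correlation). The proliferation list had all 38 members below 0 and a median of -0.19, and 0 passed either adjustment (3.04e-09; adjusted p = 0.514 with an estimated correlation). Without 24 h that list turned to the higher side with an adjusted p of 0.972. Amino acid and unfolded protein response genes, with 34 of 36 below 0 and 0 past either adjustment (6.16e-10; adjusted p = 0.415 with an estimated correlation), had a median of -0.41 at 24 h, where Chac1 stood at -1.12 and Mthfd2 at -0.82, and an adjusted p of 0.386 without 24 h. Cholesterol synthesis genes (0.0069; adjusted p = 0.690 with an estimated correlation) had 0 past either adjustment and a median of -0.31 at 24 h, with Insig1 at -0.74, and turned to the higher side without 24 h with an adjusted p of 0.0244.

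For conditioned medium the lists that missed the camera threshold were proteasome subunits (adjusted p of 0.997, median -0.01 and mean 0.00 with camera pointing up), sarcomere genes (0.259), extracellular matrix (0.997, median -0.01 and mean 0.00 with camera pointing up) and glucocorticoid targets (0.0876). Proteasome and sarcomere genes had 0 members past either adjustment by limma. In the matrix list Vcan rose over all genes and Thbs1 fell adjusted over the list alone. In the glucocorticoid list Hsd11b1, Angptl4, Cebpa and Glul rose and Fkbp5 fell adjusted over the list alone. Without 24 h the proteasome list was called higher (0.0256) and the sarcomere list lower (8.65e-04), and quantile normalization also called the sarcomere list lower (0.0462).

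Among genes of muscle wasting and muscle identity, none of those named in advance passed the test. The ubiquitin ligase gene Fbxo32 (atrogin-1) had mean changes of 0.10 ± 0.07 with LIF and 0.25 ± 0.07 with conditioned medium (adjusted p of 0.871 and 0.334), with 0.03, 0.25 and 0.46 at 4, 8 and 24 h of conditioned medium. Trim63 (MuRF1) stood at 0.07 and 0.01, and Fbxo30 at 0.03 and -0.05, for LIF and conditioned medium. The myogenic factor Myog stood at 0.03 and 0.00 and Myod1 at 0.00 and 0.13. The myosin heavy chain genes Myh1, Myh2 and Myh4 stood at -0.13, 0.00 and -0.23 with LIF and at -0.11, -0.09 and -0.06 with conditioned medium. Of the LIF receptor chains, Lifr stood at -0.07 and 0.07 and Il6st at 0.07 and 0.03, and Stat3 itself at 0.13 and 0.15. The acute phase gene Lcn2 stood at -0.13 and 0.00, and Il6 at 0.17 and 0.46, with the untreated values of both agents in the background range in all arrays and the treated ones above it at 4 h and 8 h of conditioned medium (0.75 at each). Gapdh was not analysed here.

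Markers of other cells gave no called list with either agent. For colon carcinoma epithelium the camera adjusted p was 0.824 with LIF and 0.997 with conditioned medium, where the median was 0.03 and the mean -0.01, and 0 of 12 markers passed either adjustment. Markers of macrophages and leukocytes (0.894 and 0.997) also had 0 of 11 past. Of 10 adipocyte markers (0.727 and 0.912) Cd36 fell with LIF adjusted over the list alone. Of 12 markers of fibroblasts and unfused cells (0.727 and 0.997) Pdgfra rose with both agents adjusted over the list alone. In that list Myf5 rose and Cd34 fell with LIF, and Ly6a and Pax7 rose and the smooth muscle genes Cnn1 and Tagln fell with conditioned medium.

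The difference between the agents, tested in the same fit, was widest for interferon genes. Usp18 differed by 2.43, Ifit1 by 2.19, Oasl2 by 2.14 and Irgm2 by 1.68 (conditioned medium minus LIF), and Ccl7 by 1.23. Of these Ifit1 and Irgm2 lay in the background range in all 6 LIF arrays and Usp18 in 5, so the sizes of their differences are uncertain. None passed over all genes: limma called 0 genes, with 949 at an unadjusted p under 0.05 and a smallest adjusted p of 0.393, that of Irgm2, and 0 genes under every alternative run. Camera called 6 of 21 lists for the difference. Higher with conditioned medium than with LIF was the interferon list (median difference 0.40, adjusted p of 9.02e-28), with 18 of 36 genes past adjusted over the list alone. Also higher were NF-kB targets (0.00911), with Ccl7, Ccl2 and Vcam1 past, and myogenic regulators (0.00911), with 0 past by limma. Each of these 3 had adjusted p = 0.296 with an estimated correlation. Lower were proliferation (3.70e-06), amino acid and unfolded protein response (6.88e-05) and glycolysis and hypoxia genes (0.0229), each with 0 genes past by limma and adjusted p = 0.869 with an estimated correlation. Without 24 h the NF-kB list had 0.0964, myogenic regulators 0.0927, amino acid response genes 0.876 and the glycolysis list, on the higher side, 0.912, and without 8 h the NF-kB list had 0.0712. After quantile normalization the glycolysis list had 0.0744. The cholesterol list, uncalled with all times (0.293), was called lower with conditioned medium without 4 h (0.016) or without 8 h (0.0122) and higher without 24 h (6.32e-05). Without 4 h the acute phase list was called higher (0.039) and the immediate early list lower (0.00129). The other 15 lists had camera adjusted p of 0.128 or more, among them the STAT3 list at 0.822 with a median of -0.01 and a mean of 0.03, and the matrix list at 0.422, in which Adamts5 and Lox were lower adjusted over the list alone. The colon carcinoma markers had a median of -0.02 and a mean of 0.01, and the macrophage markers a median of 0.03 and a mean of -0.01.

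**Figure D2:**
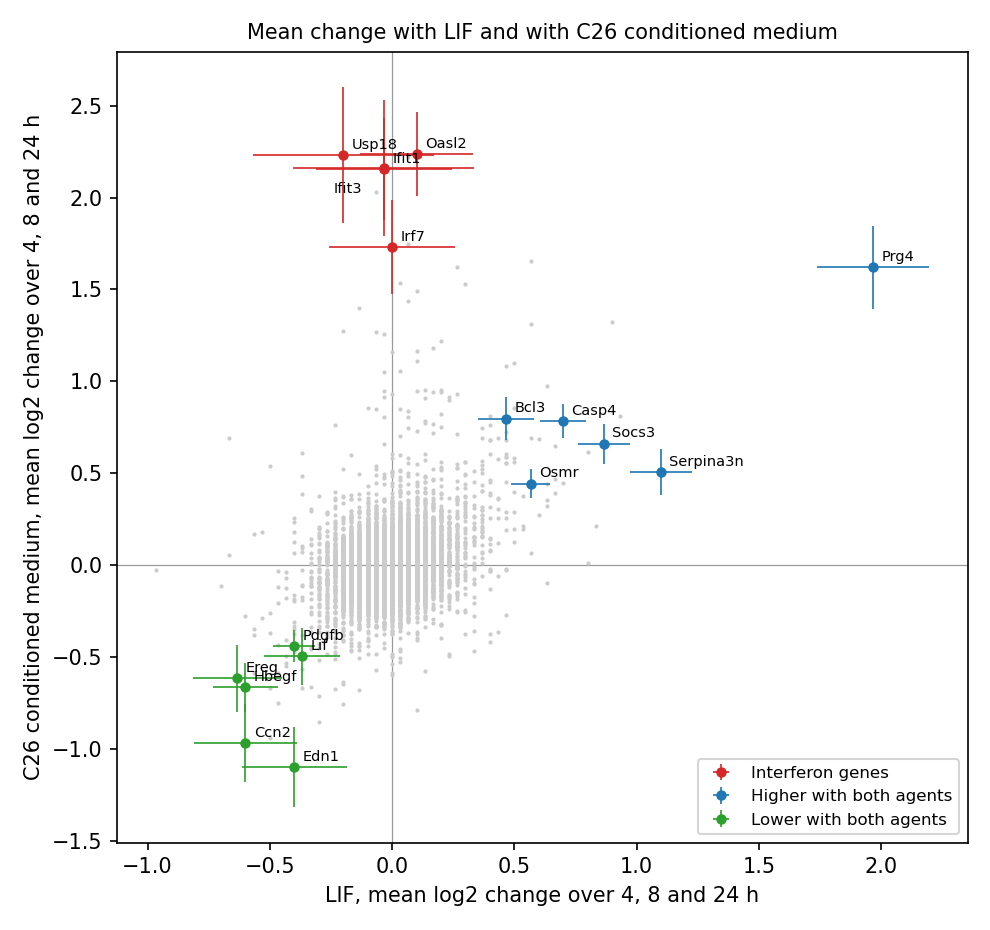
Mean log2 change over 4, 8 and 24 h with C26 conditioned medium against that with LIF, 1 point per gene, with standard errors of the fit for the genes named. Oasl2 lies at 0.10 with LIF and 2.24 with conditioned medium, and Prg4 at 1.97 and 1.62.

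Across the 21187 genes, the mean changes with the agents correlated with Pearson r of 0.239 and Spearman rho of 0.117; genes are not independent replicates. At matched times r was 0.00925 at 4 h, 0.103 at 8 h and 0.139 at 24 h. Some unmatched times had higher values, 0.231 for LIF at 24 h with conditioned medium at 4 h, 0.169 for LIF at 24 h with conditioned medium at 8 h and 0.164 for LIF at 8 h with conditioned medium at 4 h. Within an agent r ranged from -0.00229 (LIF, 4 h with 24 h) to 0.351 (conditioned medium, 8 h with 24 h). Of the 50 genes with the smallest p for LIF, 29 of the 30 higher ones were also higher with conditioned medium and 19 of the 20 lower ones were also lower. Without the dimmer 50% of genes r was 0.435, and it was 0.161 without the time whose omission lowered it most.

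The response averaged over both agents had 107 genes past the test, 81 higher and 26 lower, with 1984 at an unadjusted p under 0.05. Of the 107, 99 had the same sign in all 6 treated and untreated pairs, which the test favours by how it selects genes. At an unadjusted limma p under 0.05, 92 of the 107 changed with LIF and 32 differed between the agents. Over all 21187 genes these counts were 1445 and 949. Of the 107, 33 were also called for conditioned medium. Prg4 rose most, by 1.79 ± 0.16 (limma adjusted p of 0.00547). Components of cytokine signalling rose with it: Socs3 by 0.76 ± 0.08, Bcl3 by 0.63, Il4ra by 0.57, Il13ra1 by 0.57 and Osmr by 0.51. Serpina3n rose by 0.80, Casp4 by 0.74, Car12 by 0.71, Il33 by 0.50, Cd53 by 0.46, the platelet-derived growth factor receptor gene Pdgfra by 0.39 and the transcription factor gene Cebpd by 0.37. Oasl2 (1.17), Xaf1 (1.11), Zbp1 (0.94) and Ccl11 (0.94) completed the 5 highest of the ranked genes past the test. Oasl2 owed its mean to conditioned medium, with 0.10 for LIF. Xaf1 (0.57 with LIF and 1.66 with conditioned medium), Zbp1 (0.27 and 1.62) and Ccl11 (0.57 and 1.31) also had higher values with conditioned medium. The 5 lowest of the ranked genes past the test were the EGF receptor ligand gene Hbegf (-0.63 ± 0.09, adjusted p of 0.0252), Ccl17 (-0.46), Klhdc8a (-0.45), Apol10a (-0.44) and Pdgfb (-0.42). Cx3cl1 (-0.41) and Tgfb1 (-0.27, adjusted p of 0.0451) also fell. Ccn2 (-0.78, adjusted p of 0.0593), Edn1 (-0.75, adjusted p of 0.0734) and Ereg (-0.62, adjusted p of 0.0757) missed the test. The call count was 0 without 4 h, 0 without 8 h and 0 without 24 h. It was 4 without a variance trend, 51 from the authors' deposited table of fold changes, 284 at a threshold of 0.10 and 0 after rounding conditioned medium values to 1 decimal.

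**Figure D3:**
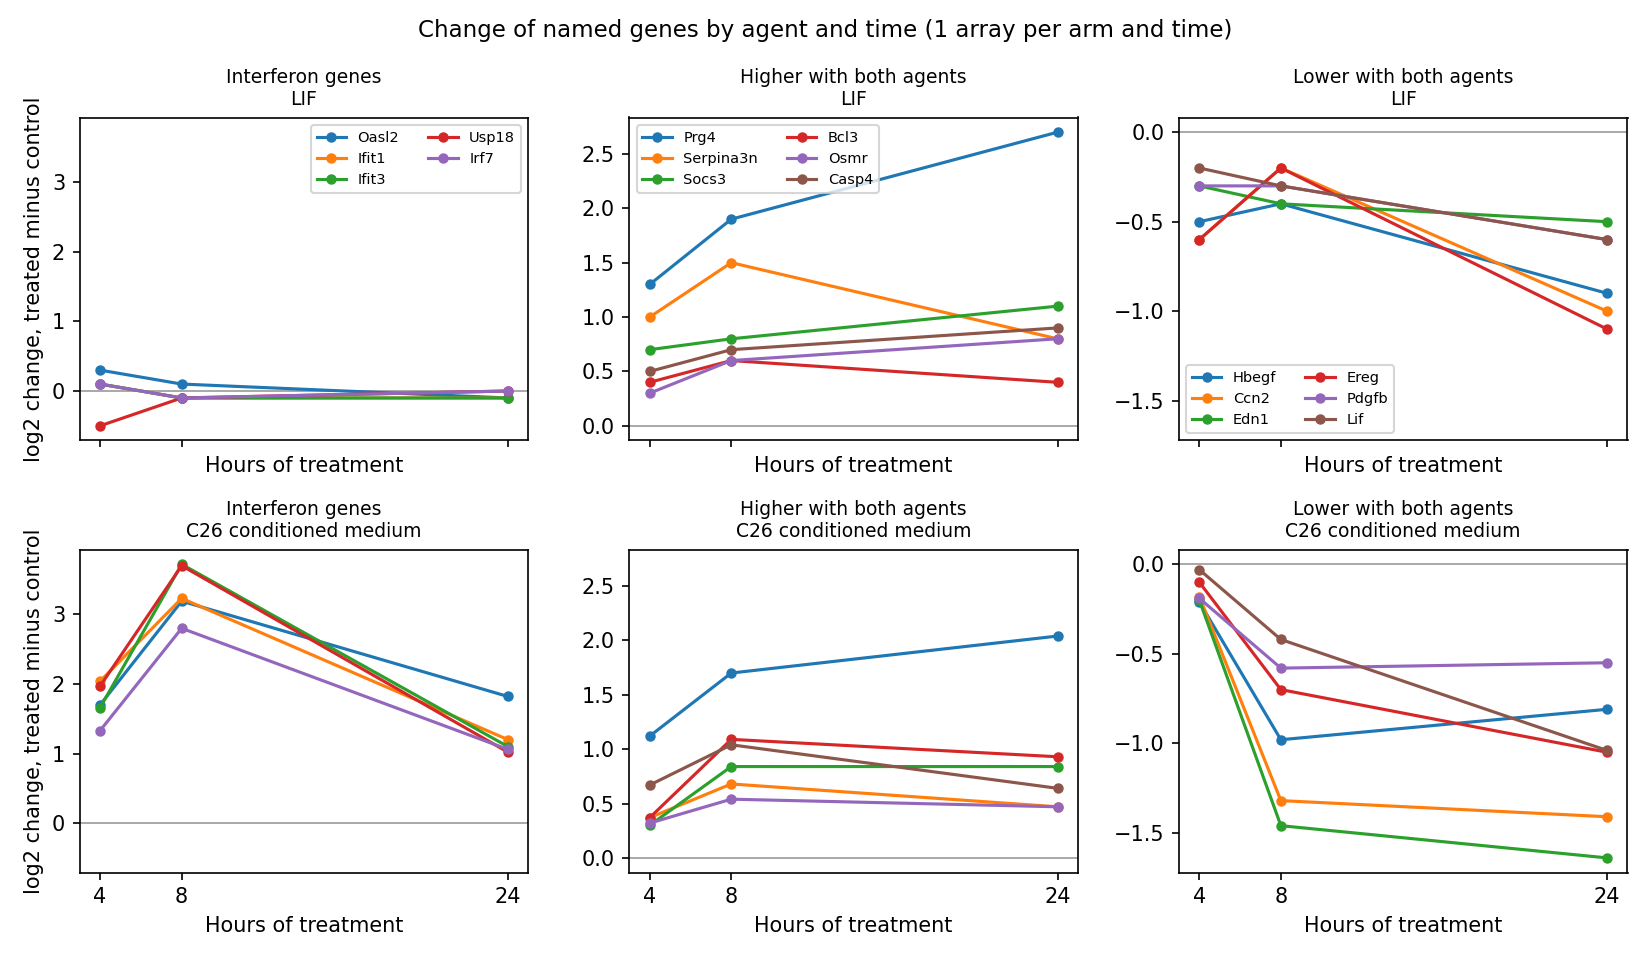
Log2 change, treated minus untreated, of named genes at 4, 8 and 24 h for LIF (top row) and C26 conditioned medium (bottom row), 1 array per arm and time, so without error bars. Prg4 reached 2.7 with LIF at 24 h, Ifit3 3.72 with conditioned medium at 8 h, and Edn1 -1.64 with conditioned medium at 24 h.

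By gene list, 7 of 36 STAT3 list members rose over all genes in the averaged response, among them Socs3, Bcl3, Il4ra, Osmr, Cebpd and Hif1a, and 14 rose and 4 fell adjusted over the list alone. Of 36 immediate early and ERK pathway genes Hbegf and Dusp4 fell over all genes, and 19 fell and 0 rose adjusted over the list alone. Of 21 TGF-beta and activin targets Tgfb1 fell over all genes, and 13 fell and 3 rose adjusted over the list alone. In the atrophy list Txnip, Map1lc3b and Mt2 rose over all genes, and Fbxo32 (0.17) was among 7 that rose adjusted over the list alone. Camera was not run on this average for the 21 lists.

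Between 4 h and 24 h the responses to both agents shifted to lower levels of cell cycle genes. Arrays of 24 h did not share a scale with those of 4 h. Each change was taken within a time, but an effect of time cannot be fully told apart from one of array scale. In a fit with a time effect shared by the agents, limma called 85 genes, 25 higher and 60 lower at 24 h than at 4 h, with 1577 at an unadjusted p under 0.05. Of 38 measured proliferation genes 13 fell over all genes and 35 adjusted over the list alone, with a median of -0.54 and all 38 below 0. The thymidylate synthase gene Tyms fell by 0.81, the mitotic kinase genes Bub1 by 0.75 and Plk1 by 0.69, Mki67 by 0.65, Ccna2 by 0.53 and Cdk1 by 0.50, and the cyclin D1 gene Ccnd1 fell by 0.85 ± 0.10 (adjusted p of 0.00573). In the arrays themselves the median of the proliferation list was 0.20, 0.00 and -0.30 at 4, 8 and 24 h of LIF and 0.02, -0.03 and -0.55 of conditioned medium.

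Of the ranked genes past the test, Ptgfr rose most from 4 h to 24 h (1.43 ± 0.21, limma adjusted p of 0.0159). Next among them were Prg4 (1.16 ± 0.15), the complement C1 inhibitor gene Serping1 (0.94 ± 0.11), the collagen-binding proteoglycan gene Dcn (0.91 ± 0.11) and Mest (0.88 ± 0.11). Ly6a rose by 0.79, Hsd11b1, which reactivates glucocorticoids, by 0.79, Angptl4 by 0.62, Il4ra by 0.48, Col3a1 by 0.47 and the titin gene Ttn by 0.42. Pcdha11 fell most of the ranked genes past the test (-1.82). It lay at a mean level of 3.28 in the background range and in a family of near-identical copies, so its value is uncertain. Next among them were the thrombin receptor gene F2rl2 (-1.0), the adhesion molecule gene Alcam (-0.97), Mgll (-0.96) and Igha (-0.94). Col8a1 (-0.92), Cnn1 (-0.70) and Tagln (-0.41) fell as well. With 2 residual degrees of freedom the count of 85 depended on the settings: it was 0 without a variance trend, 26 after quantile normalization, 136 with robust variances, 138 with arrays centred on their medians and 165 at a threshold of 0.10.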

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

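Values in this section come from tests set in advance, with exceptions chosen only after the result was seen. These are the tests of normalization, of carry-over, of LIF as the source, of rounding, of the shared spread and of YAP and TEAD targets. The lists that differed between the agents drew attention because a difference between groups was tested for them and passed. Camera adjusted p for conditioned medium minus LIF was 9.02e-28 for the interferon list (median 0.40), 0.00911 for NF-kB targets and chemokines (0.09), 0.00911 for myogenic regulators (0.07), 3.70e-06 for proliferation (-0.16), 6.88e-05 for amino acid and unfolded protein response genes (-0.12) and 0.0229 for glycolysis and hypoxia genes (-0.04). With an estimated correlation the first 3 had 0.296 and the last 3 had 0.869. The 85 genes past the test for 24 h minus 4 h drew attention as a difference between times shared by the agents.

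A gene that changed one way with LIF and the other way with conditioned medium at all 3 times also drew attention, by a rule without a test. These were the defensin gene Defb12, with a log2 difference of 1.36, the Notch target gene Heyl (0.37), the immediate early gene Egr3 (0.26), the prolyl hydroxylase gene P4ha2 (-0.27) and the matrix protease gene Adamts5 (-0.43). The opposite signs were not tested. Such opposite signs occurred in 165 of 6416 genes with a nonzero value in all pairs, or 2.57%, where independent signs would give 3.12%, and Defb12 lay in the background range in all 3 untreated conditioned medium arrays. The size of the difference had an adjusted p of 0.40 for Defb12 and 0.967 for Heyl.

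The first pattern weighed is the interferon list, higher with conditioned medium and not with LIF. After quantile normalization of the 12 arrays together the median difference was 0.38 against -0.05 to 0.04 in random lists. Treated and untreated arrays of a pair had near-equal medians before this step, so it cannot exclude the authors' normalization. For a high untreated level in the LIF experiment, ranks in the treated conditioned medium arrays were set against ranks in the untreated LIF arrays. The median rank of the list was higher in the former at each time, by 8.34% of genes where least. Of the 36 members 11 ranked lower at 4 h, 7 at 8 h and 9 at 24 h. These ranks argue against that explanation for the list as a set. They compare separate experiments, so it is not excluded. RNA carried over in the medium would raise the genes no more at 8 h than at 4 h, and the median rise between them was 0.56. The median of -0.40 for LIF minus conditioned medium defines the pattern. With LIF alone the 20 members above background in all untreated LIF arrays had a median of 0.02 (random lists -0.05 to 0.03). At 4 h of LIF the whole list had a median of 0.10, at the upper end of random lists (0 to 0.10). The averaged values argue against LIF in the medium as the only source for these 20 members at the dose used. That source is not excluded, as the experiments were separate and no measure of LIF in the medium was used here. Prg4 and Socs3 had values at least as high with LIF as with the medium. Other shared genes were higher with the medium, such as Casp4 (0.70 with LIF, 0.78 with the medium) and Ptgfr (0.90 and 1.32).

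The second pattern is the count of 0 genes for LIF against 46 for conditioned medium. Rounding the conditioned medium values to 1 decimal, as the LIF values are, brought the 46 to 0, so rounding remains a possible cause. Spread shared with the conditioned medium arrays was tested with the LIF arrays alone, which gave 0 genes, and this cannot tell. The counts therefore do not rank the agents.

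The third pattern is the fall of 26 genes in the mean response to both agents, among them Hbegf. All 26 stayed past the test after quantile normalization. For the reason given for the first pattern, this cannot exclude the authors' normalization for them. Ccn2 and Edn1 did not pass the test and are not among them. A list of 18 other YAP and TEAD targets, written after falling genes were seen and before the list was tested, had a median of -0.06. Random lists gave -0.03 to 0.03. Its members Ankrd1 and Gadd45a were already in the TGF-beta and atrophy lists, so their values were at hand. The camera p of the list was 1.76e-05, and 0.0196 with an estimated correlation, so lower YAP and TEAD activity stays open. Lower TGF-beta and ERK signalling stay open too, and their lists had medians of -0.20 and -0.12 in the mean response.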

How the results depend on the processing

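Noise within the rounding of the LIF values and rounding of the conditioned medium values to 1 decimal were chosen only after seeing the data. For LIF, where limma called 0 genes, the count was 8 without the dimmest 25% of genes, 12 with robust variances, 12 after quantile normalization and 28 at a threshold of 0.10. Noise within the rounding gave 11. The smallest limma adjusted p was 0.0559 in the main fit and 0.0221 with noise within the rounding. It was 0.0268 with robust variances, 0.0368 after quantile normalization and 0.0484 without the dimmest 25% of genes. The cause of the changed counts was not tested. The remaining settings left 0.

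For conditioned medium, with 46 genes, the count was 25 without the dimmer 50% of genes, 0 without a variance trend, 25 with robust variances, 76 at a threshold of 0.10, 13 from the authors' fold changes and 0 in the 6 arrays of that experiment. With 1 time left out it ranged from 0 to 1. Rounding to 1 decimal gave 0. A fit without 1 time, or on 6 arrays, has fewer residual degrees of freedom by construction. After quantile normalization and after leaving out the dimmest 25% of genes, 36 and 45 genes were called, of which 36 and 42 were among the 46. The difference between the agents had 0 genes in every setting.

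For the mean response, with 107 genes, the count was 4 without a trend, 284 at a threshold of 0.10, 51 from the authors' fold changes, 0 to 0 with 1 time left out, and 0 with conditioned medium values rounded to 1 decimal. For 24 h minus 4 h, with 85 genes, it was 0 without a trend, 136 with robust variances, 26 after quantile normalization, 138 after centring on the median and 165 at a threshold of 0.10. No scaling moved the median change of all genes at a time by more than 0.02.

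At 1.5-fold and 3-fold the counts were 114 and 0 for LIF at 4 h, 104 and 1 at 8 h, and 262 and 3 at 24 h, and 93 and 6 for conditioned medium at 4 h, 250 and 29 at 8 h, and 551 and 16 at 24 h. Without the dimmest 25% of genes 7 were past 2-fold for LIF at 4 h and 6 at 8 h.

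The correlation across genes of the mean changes, 0.239, was 0.117 as Spearman, 0.435 without the dimmer 50% of genes, and ranged from 0.161 to 0.207 with 1 time left out. That all 3 lie below the value with all times was not examined further.

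Of the gene lists, camera with an estimated correlation called 0, 0 and 0 and fry 0, 0 and 0 for LIF, conditioned medium and their difference, against 6, 13 and 6. With 1 time left out the number ranged from 5 to 6, from 10 to 11 and from 3 to 9. The proliferation list with conditioned medium had adjusted p from 1.58e-09 (without 8 h) to 0.972 (without 24 h), where it turned to higher. The cholesterol list with conditioned medium ranged from 2.17e-06 (without 8 h) to 0.0244 (without 24 h), where it turned to higher, and the glycolysis and hypoxia list in the difference from 1.08e-04 (without 8 h) to 0.912 (without 24 h), where it also turned.

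Over all settings, 69 of 121 counts and correlations stayed and 52 moved. Of 441 results for gene lists 360 stayed, 67 were weaker, 11 stronger and 3 reversed. A list uncalled in both settings counted as stayed. With an estimated correlation, and with fry, 25 of 63 were weaker and the 38 that stayed were uncalled lists. Of 230 for named genes at a time 208 stayed and 22 moved. Of 1822 for named genes in a fit 1465 stayed, 201 were weaker, 62 stronger, 94 moved and 0 reversed. Only a gene past the test in the main fit could count as reversed, so no result for the LIF response could.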

Other observations

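Some genes move with LIF and conditioned medium alike that are not usual members of a STAT3 list. Prg4 (1.97 with LIF, 1.62 with conditioned medium), Ptgfr at 24 h (1.5 and 1.91), Hsd11b1 at 24 h (0.9 and 0.90) and Car12 (0.80 and 0.61) are such genes, chosen after their values were seen. Prg4 encodes a lubricating glycoprotein of joints and tendon sheaths, Ptgfr a receptor for a prostaglandin that acts on myotube growth, Hsd11b1 an enzyme that makes active glucocorticoid inside the cell, and Car12 a membrane carbonic anhydrase. Of these only Prg4 and Car12 passed the test in the mean of both agents.

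The tests of normalization, of carry-over, of LIF as the source, of rounding and of the shared spread below were chosen only after the result was seen. The rise of interferon genes with conditioned medium (8 h median 0.92) was 0.56 for 8 h over 4 h, where carried-over RNA would give no further rise. The difference from LIF was 0.38 after quantile normalization, and the smallest median rank difference against untreated LIF arrays was 8.34%. These last values do not exclude the authors' normalization or a high untreated level in the LIF experiment. As a hypothesis, the tumour medium may carry an interferon or a nucleic acid that induces one. With LIF alone the 20 members above background in all untreated LIF arrays had a median of 0.02, within the -0.05 to 0.03 of random lists. These values argue against LIF in the medium as the only source for them at the dose used. They do not exclude it, as the experiments were separate and no measure of LIF in the medium was used here. The median of -0.40 for LIF minus conditioned medium is the comparison that defines the pattern and adds no separate test. LIF acting together with another factor was not tested. Blocking the type I interferon receptor on the myotubes, or measuring interferon in the medium, would test it. Contamination of the tumour cells or of the medium by microbial products was not tested here and could give the same genes; an assay for mycoplasma and endotoxin would separate it.

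Socs3 and Osmr were among the genes that rose in the mean of both agents, which the LIF arrays carry in part. With conditioned medium alone Socs3 stood at 0.30 at 4 h and 0.66 on average, and missed the test (limma adjusted p of 0.0557). As a hypothesis, the medium may hold LIF or another ligand of the gp130 receptor chain, and this was not tested. Of the ways to swap the labels within pairs for the mean response, 1 of 32, the true one, gave 107 genes and the highest other gave 0. A swap turns a real change into spread, so low counts were likely in the other splits. The pairs are times of each agent with 1 pooled array per arm, not replicates, so the swaps cannot exclude chance. An antibody against LIF in the conditioned medium would show which of the genes that rose need LIF, and whether the interferon genes stay high without it.

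The fall of Hbegf in the mean of both agents leaves lower YAP and TEAD activity open. A list of 18 other targets of these factors, written after falling genes were seen, had a median of -0.06. Of these 4 fell adjusted over the list alone, and 3, among them Ankrd1, lay above 0. The 26 genes that fell in that mean all stayed after quantile normalization; Ccn2 and Edn1, known targets with low values, did not pass the test. The median of the YAP and TEAD list is small, and lower TGF-beta or ERK signalling could lower the same genes. The lists of those pathways had medians of -0.20 and -0.12 in the mean response. Staining for YAP in nuclei and for phosphorylated SMAD2 and ERK after LIF would tell these apart.

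Rounding of the LIF values to 1 decimal, with 0 conditioned medium genes left after the same rounding, may account for the lack of genes past the test with LIF, and the test of the spread shared with the conditioned medium arrays, also 0, cannot tell. Values of the LIF experiment with more decimals would settle it.

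For the other results the label splits cannot exclude chance either, being too few for a share under 0.05. For LIF 1 of 4 splits, the true one, had 1445 genes at an unadjusted p under 0.05 and the highest other 1249. For conditioned medium 2 of 4 splits had at least the true 1585, the highest other 1738, while past the test the true split had 46 genes and each other 0. For 24 h minus 4 h the true split, 1 of 18, had 85 genes past the test and the highest other 10. For conditioned medium minus LIF 5 of 10 had at least the true 949, where chance gives 1059. A split that groups LIF at 4 h with conditioned medium at 8 h and 24 h had 2172, and the source of that count was not tested.

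Replicate cultures at 24 h, with wells kept apart, would give the spread these pools hide. Whether wasting follows can be read from myotube width beside Fbxo32, whose values with conditioned medium were 0.03, 0.25 and 0.46 at 4, 8 and 24 h and did not pass the test.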
